A study of Mus musculus with 15 samples.

How the data were processed

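Total RNA from spheres was isolated with ISOGEN II, samples with an RNA integrity number over 8 were used, and 40 or 200 ng were labelled with Cy3 by the Low Input Quick-Amp method, per the labels' protocols, which do not say which array received which amount. The labels put 7 arrays into 4 biological replicates of WT primary spheres and 8 arrays into 4 biological replicates of TH-MYCN passaged spheres, all from E13.5 embryos. For the TH-MYCN arrays the group was taken from titles and source names, which the series design bears out; descriptions and cell type call the same arrays primary spheres. The biological replicates are called individual in the design text, without saying whether they came from separate embryos or litters, so that p-values measure the spread between these replicates.

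The deposited scanner files hold, per the file headers, 1 array each, extracted with Feature Extraction 11.0.1.1 under a one-colour gene expression protocol, on a mouse 8x60K-format design built on mm9. Their processed signal is an intensity on a linear scale, background-subtracted and detrended within the array by that software and not normalized between arrays, per the file headers. The raw median intensity of each spot and of its local background, and flags of 0 or 1 for spots well above background, saturated or outlying, were deposited beside it. The authors' deposited series matrix holds log2 values: set against the scanner values, differences between arrays had slopes of 1 to 1.0003 and r of at least 0.99984 over 55681 probes, each probe averaged 0 over the 15 arrays, and each array's shift lay within 0.033 log2 of its 75th percentile. Scale, centring and direction of the matrix thus follow from the values, and the authors' description of these steps is not given in the sources used here. The matrix medians were -0.078, 0.051, -0.132, -0.050, -0.128, -0.272 and -0.148 for the WT arrays and 0.177, 0.237, 0.139, 0.085, -0.010, -0.045, -0.0023 and -0.036 for the TH-MYCN arrays, in the order of replicates.

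For the main values, log2 of the processed signal was reduced by each array's 75th percentile over non-control probes, which was 465 to 785 on the linear scale. Control spots were left out, outlier-flagged spots (93 to 230 per array) were set to missing, spots of a probe were averaged, and 0 spots were saturated. The arrays of a replicate were averaged into 1 value, as technical repeats. Probes were kept if well above background on at least 1 array of at least 3 of the 4 replicates of either group, which left 32206 probes and, with the brightest probe standing for each gene, 14701 genes. Among 3886 genes with several tested probes, 1 had probes called in both directions. The files carry no gene names. Of 55681 probes 28685 carried a RefSeq accession, and 27235 of these matched 1 current symbol without versions in a RefSeq gene table of assembly GRCm38.p6, 0 matched several and 28446 probes stayed unnamed, giving 20660 symbols. The design's build and the table's differ, so no coordinates are given. Xist and Y-linked genes were left out of all named genes, since embryo sex is not given.

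Groups were compared gene by gene with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, on 4 against 4 replicate values with group as the only term, and p-values were adjusted by Benjamini-Hochberg over all genes, with 0.05 as the threshold. Gene lists were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over the 30 lists. A gene not well above background on any array of 1 group has only a bound: the mean of the bright group against the mean, in the dim group, of the higher of each array's lowest signal well above background and the probe's own signal. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

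The design, the alternatives other than those named as added, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest rises and 10 largest falls among called genes that are well above background in every replicate and whose groups do not overlap, and the 4 largest bounds in each direction (3 genes qualified as rises). It adds in each list the 2 members with the lowest adjusted p among those that rose and the 2 among those that fell, or the 2 brightest where none passed, and Mycn, Myc, Mycl, Ezh2, Suz12 and Eed, and it leaves out clone and predicted-gene names. Of the genes that the rule selects, 1 is not reported here.

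The 30 lists were compiled from general knowledge, not from these samples: MYC targets of ribosome biogenesis and of metabolism and growth, PRC2 targets among developmental transcription factors, Hox clusters, and signalling genes with cell cycle inhibitors, PRC2 and PRC1 components, DNA replication, mitosis, sympathoadrenal lineage, neuronal differentiation, neural crest and Schwann cell precursors, fibroblast and mesenchyme, smooth muscle and pericytes, endothelium, macrophages and leukocytes, erythroid cells, adrenal cortex and steroidogenesis, epithelium, p53 pathway, Notch pathway, hypoxia and glycolysis, amino acid stress response, antigen presentation and interferon response, cytosolic ribosomal proteins, oxidative phosphorylation, cholesterol biosynthesis, immediate early genes, neuroblastoma-associated genes, stem and progenitor cell genes, and imprinted genes. Cd68, Hbb-b1, Ahsp, Pycr1, Mx1 and H19 had no named probe. Members shared with another list numbered 11 in the neuroblastoma list, 5 in the stem cell list, 4 in the PRC2 signalling list, 3 in the sympathoadrenal and imprinted lists, 2 in the neural crest and Notch lists, 1 in the MYC metabolism, mitosis, fibroblast, smooth muscle and immediate early lists, and 0 in the others.

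The arrays lay on 2 slides, each of which held both groups (3 WT and 4 TH-MYCN arrays on slide 1, 4 and 4 on slide 2), and the scan coincided with the slide. Alternatives were other scalings (quantile normalization, the median of probes detected on all arrays, spike-in controls, cyclic loess, normexp with an offset of 50 followed by quantile normalization, and the series matrix values), other filters on dim probes, the median of a gene's probes or probes in place of genes, the first or last array of each replicate, all 15 arrays with duplicateCorrelation, the slide or the replicate number as a block, a trended robust variance, array weights, a test against a change of 1.2-fold (treat), an adjusted p under 0.01, fry, camera with an estimated correlation, and each replicate left out in turn. Normexp was planned on the mean spot signal, which the files used here do not carry, and was run on the median spot signal and the local background. The arrays of slide 2 are the last arrays of the replicates, so the fit within slide 2 is the planned fit on last arrays. Chosen after seeing the data were the fit within slide 1, which holds no array of WT replicate 3, the fit without WT replicates 3 and 4, and the fit in which spots at the floor on 1 array take the value of the replicate's other array.

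The fit was tested on simulated values of the 14701 genes, drawn around each gene's WT mean with the larger of its SDs in the 2 groups. Of 50 genes changed by 0.5 log2 it recovered 4 (8%), of 49 changed by 1 log2 22 (44.9%), of 50 changed by 2 log2 44 (88%) and of 50 changed by 4 log2 50 (100%), and 6 of 14467 unchanged genes were called. A list shifted by 0.6 log2 had an adjusted p of 8.6e-28, and 0 other lists of the 30 passed. The simulation changed 200 genes and 1 list, whereas 3131 higher and 2440 lower genes were called in the real data. Adjustment over so few changed genes is stricter, so the recovered shares are not those of the real comparison. The genes were drawn independently of one another, so the simulation does not show how often camera calls lists with correlated members. The estimated correlation in the real data was 0.75 for MYC targets of ribosome biogenesis.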

Results

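Messenger RNA was measured on 15 one-colour Agilent arrays in spheres, free-floating clusters of cells grown in culture, from the SMG of mouse embryos at E13.5. The labels do not spell out SMG, which in work on this mouse names the superior mesenteric ganglion, a sympathetic ganglion. TH-MYCN mice carry a human MYCN transgene under the tyrosine hydroxylase promoter and develop neuroblastoma, a tumour of the sympathetic lineage. The wild-type (WT) spheres came from a first culture and the TH-MYCN spheres had been passaged, so genotype and passage changed together and each difference reported here is one of both at once. The labels of the TH-MYCN arrays differ among themselves: titles and source names speak of passaged spheres, whereas descriptions and cell type speak of primary spheres. Each group held 4 biological replicates, on 7 arrays for WT and 8 arrays for TH-MYCN, with 1 array for WT replicate 3 and 2 arrays for each of the others. Between 50.8% and 59.7% of the 55681 probes on an array were well above background, and the 4 replicates per group limit the precision.

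Arrays of the same replicate lay close together. The SD between them had a median over genes of 0.055 log2, against 0.159 between the WT replicates and 0.190 between the TH-MYCN replicates. Pearson's r across genes, which are not independent replicates, was 0.978 to 0.997 between arrays of a replicate, 0.966 to 0.994 between replicates of a group and 0.896 to 0.967 between the groups. The first principal component held 80.1% of the variance and parted the groups, with the WT replicates at -34.2, -55.0, -86.9 and -97.6 and the TH-MYCN replicates between 62.9 and 78.1. The second held 8.29% and set TH-MYCN replicate 1, at -54.1, apart from the other TH-MYCN replicates, at 14.1 to 27.2. The arrays of TH-MYCN replicate 1 had the lowest 75th percentiles, 465 and 498 against 556 to 785 on the others. They also had the lowest shares of probes well above background, 50.9% and 50.8%. Whether this lower signal sets the replicate apart was not tested.

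Of the MYC family, the mouse gene Mycn gave a signal of 4.75 ± 0.12 (SD, n = 4) in WT and 4.67 ± 0.24 (SD, n = 4) in TH-MYCN spheres, in log2 units relative to each array's 75th percentile. Myc, the gene of the closely related transcription factor c-MYC, fell by 2.45 ± 0.25 (SE) log2, which is 5.46-fold, with an adjusted p of 4.0e-04 in limma. Mycl, the third member of the family, differed by -0.13 ± 0.16 (SE) log2 (adjusted p = 0.550). All 3 genes were well above background on every array of both groups. The difference in Mycn was -0.07 ± 0.13 (SE) log2 (adjusted p = 0.683), and -0.09 with the slide as a block and within each of the 2 slides. Under quantile normalization, cyclic loess and normexp with quantile normalization it was -0.29, -0.32 and -0.30 and passed the test as lower, and its adjusted p ranged from 0.0143 to 1 over all alternatives. The level of the human transgene was not analysed here, and whether the mouse Mycn probe also binds its transcript is not given in the sources used here.

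The comparison of passaged TH-MYCN with primary WT spheres asks which genes differ at an early stage of the disease, and the series title places the targets of MYC and of PRC2 (polycomb repressive complex 2) at its centre. The 10 largest falls given here are those among genes well above background on at least 1 array of every replicate of both groups, and of these Serpinh1 and Hoxa7 were so on 6 and Col6a2 on 7 of the 8 TH-MYCN arrays. Col1a2, a chain of type I collagen, fell by 10.21 ± 0.62 (SE, n = 4 and 4) log2. Serpinh1, the collagen chaperone HSP47, fell by 8.01 ± 0.56 (SE) and Sparc, a matrix glycoprotein, changed by -7.60 ± 0.43 (SE), with adjusted p of at most 8.1e-05 for the 3 genes. Col6a1, Col5a1, Serpinf1, Nid1, Col6a2 and Fkbp10, which encode secreted and matrix proteins or help to fold collagen, had changes of -7.25 to -6.17 log2. Col3a1, Mgp, Col6a3 and Lum, likewise matrix genes, were not well above background on any TH-MYCN array and were at least 899.6-, 478-, 431- and 346-fold lower there. The homeobox gene Hoxa7, likewise among these 10, fell by 8.87 ± 0.17 (SE) log2 (467-fold, adjusted p = 1.7e-07).

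The 10 largest rises were taken by the same rule. Gad2, which makes the transmitter GABA, rose by 3.97 ± 0.45 (SE, n = 4 and 4) log2 (15.7-fold, adjusted p = 6.1e-04). Adcyap1, which encodes the neuropeptide PACAP, rose by 3.94 ± 0.26 (SE) and Fgf15, a secreted growth factor, by 3.82 ± 0.45 (SE). Il2rg, the common gamma chain of interleukin receptors, Tafa4, a secreted neurokine, Cacna2d3, a calcium channel subunit, Mir9-3hg, a host transcript of the neural microRNA miR-9, Pnoc, the nociceptin precursor, and Ecel1, a neuronal peptidase, rose by 2.85 to 3.30 log2. Neurod1, a neuronal basic helix-loop-helix factor, was not well above background on any WT array and at least 27.6-fold higher in TH-MYCN spheres. It was followed by Lingo3 (at least 4.59-fold) and the GABA transporter Slc6a11 (at least 2.64-fold), and these were the only 3 genes that met the rule for such rises. Pou4f2, a POU homeobox factor of sensory neurons, rose by 3.30 ± 0.96 (SE) log2 (adjusted p = 0.0286). Its adjusted p was 0.0710 without WT replicate 3, 0.0755 without WT replicate 4 and 0.0621 without TH-MYCN replicate 3, in a range of 0.0023 to 0.20 over all alternatives.

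Of 14701 genes tested with limma, 3131 were higher and 2440 lower in TH-MYCN spheres at an adjusted p under 0.05, 9130 did not pass, and 56.2% of the calls were higher. Of these, 190 genes were at least 2-fold higher and 1537 at least 2-fold lower. The 2-fold counts were 87 and 897 under normexp with quantile normalization, 152 and 687 over genes well above background on every array of both groups, 125 and 1714 under cyclic loess and 122 and 1009 without both WT replicates 3 and 4. In the main values 1 gene rose and 296 fell at least 16-fold. Of the lower genes 493, and of those at least 2-fold lower 483, were not well above background on any TH-MYCN array, against 13 and 11 of the higher genes on the WT arrays, so that their fitted folds are not bounds. The values of the groups did not overlap for 6024 genes (41.0%, against 2.86% by chance). With the slide as a block 3654 genes were higher and 2394 lower, on slide 1 alone 1369 and 1721, and on slide 2 alone 2911 and 2288. Slide 1 holds no array of WT replicate 3, and without that replicate on either slide 1491 genes were higher and 1820 lower. The median log2 difference of all genes was 0.13, and between -0.06 (cyclic loess) and 0.13 (series matrix values) under other scalings, so some gene lists are also given relative to it. For the sympathoadrenal, neuronal and cholesterol lists the medians of 0.11, 0.07 and 0.05 became -0.02, -0.06 and -0.08 relative to it. Cyclic loess gave 1564 higher and 3492 lower genes (30.9% higher), and the number of higher genes was 1491 without WT replicate 3, 1546 without WT replicate 4 and 2012 without TH-MYCN replicate 2. Without both WT replicates 3 and 4, which had the highest levels of fibroblast markers, 439 genes were higher and 1304 lower.

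**Figure D1:**
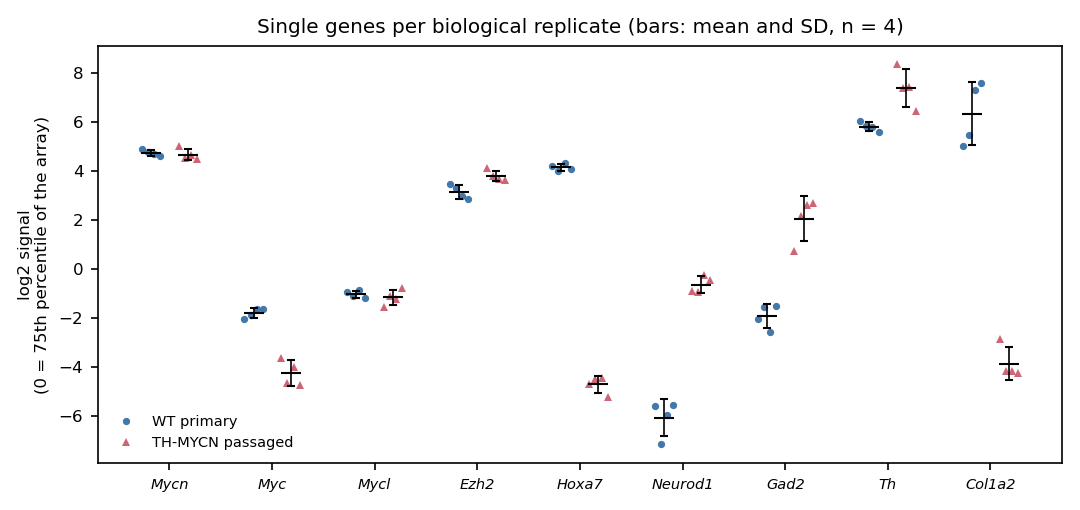
Log2 signal relative to each array's 75th percentile (vertical axes) of single genes in the 4 WT primary and 4 TH-MYCN passaged replicates (points), with the mean and SD of each group. Mycn lies at 4.75 in WT and 4.67 in TH-MYCN spheres, whereas Hoxa7 lies at 4.16 and -4.71.

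Genes that MYC proteins are known to activate for making ribosomes rose together. Of the 35 members of this list 34 rose and 1 did not pass (35 rose adjusted over the list alone). Gnl3, the nucleolar protein nucleostemin, rose by 0.87 ± 0.11 (SE, n = 4 and 4) log2 and Ppan, a ribosome assembly factor, by 0.71 ± 0.09 (SE), with adjusted p of 8.5e-04 and 8.4e-04. The list's median was 0.65 log2, 0.52 above that of all genes (camera adjusted p = 4.9e-11, and adjusted p = 0.396 with an estimated correlation). It was 0.65 with the slide as a block, 0.64 on slide 1 and 0.65 on slide 2. Of the 38 MYC targets of metabolism and growth 24 rose, 1 fell and 13 did not pass (27 rose and 1 fell adjusted over the list alone). Srm, which makes the polyamine spermidine, rose by 0.89 ± 0.11 (SE) and Shmt1, an enzyme of one-carbon metabolism, by 0.98 ± 0.13 (SE), while the cyclin gene Ccnd2 fell by 5.95 ± 0.49 (SE), a value that rests in part on background, since it was well above background on 4 of 8 TH-MYCN arrays. This list's median was 0.51, 0.38 above all genes (camera adjusted p = 2.6e-05, and adjusted p = 0.507 with an estimated correlation), and 0.51, 0.45 and 0.52 with the slide as a block and on slides 1 and 2. In the same replicates the mean over 28 fibroblast and mesenchyme markers was 1.90 ± 1.14 (SD, n = 4) in WT and -4.34 ± 0.11 (SD, n = 4) in TH-MYCN spheres. Under cyclic loess the medians of the MYC lists were 0.43 and 0.27, and quantile normalization and normexp brought that of the metabolism list to 0.31 and 0.28. Without WT replicates 3 and 4 they were 0.51 and 0.38.

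Genes of the cell cycle were higher as well. Of 35 genes of DNA replication 30 rose and 5 did not pass (32 rose adjusted over the list alone), among them Cdc6, which loads the replicative helicase, at 0.86 ± 0.15 (SE, n = 4 and 4) log2, and Mcm10, an initiation factor, at 0.73 ± 0.13 (SE). The list's median was 0.61, 0.48 above all genes (camera adjusted p = 3.1e-07, and adjusted p = 0.506 with an estimated correlation), and 0.60, 0.55 and 0.56 with the slide as a block and on slides 1 and 2. Of 30 genes of mitosis 20 rose and 10 did not pass (24 rose adjusted over the list alone). Ube2c and Cdc20, which act in the anaphase-promoting complex pathway, rose by 0.78 ± 0.11 (SE) and 0.79 ± 0.13 (SE). The mitosis median was 0.55, 0.42 above all genes (camera adjusted p = 1.2e-05, and adjusted p = 0.569 with an estimated correlation), and 0.54, 0.47 and 0.56 in the slide-blocked and within-slide fits. Within the WT group, the replicates with fibroblast marker means of 0.52 and 1.45 had mitosis means of 3.33 and 3.25, and those with 2.57 and 3.05 had 2.91 and 2.80. Without WT replicates 3 and 4 the medians were 0.40 for DNA replication and 0.33 for mitosis. They were 0.38, 0.35 and 0.38 for DNA replication and 0.34, 0.31 and 0.31 for mitosis under quantile normalization, cyclic loess and normexp.

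Among genes that PRC2 is known to hold silent in embryonic stem cells, part of each list was lower in TH-MYCN spheres. The other tested members rose or did not pass. Of 39 Hox genes 28 were tested, of which 21 fell, 1 rose and 6 did not pass (21 and 1 adjusted over the list alone). Hoxa7 fell as given above, Hoxa5 was at least 14.0-fold lower (not well above background on any TH-MYCN array, adjusted p = 2.8e-06), and Hoxc4 rose by 0.97 ± 0.16 (SE, n = 4 and 4) log2. The Hox median was -3.69 (-2.55 with genes below background at their bounds), -3.82 relative to all genes, and -3.70, -3.44 and -3.71 with the slide as a block and on slides 1 and 2 (camera adjusted p = 1.3e-14, and adjusted p = 0.142 with an estimated correlation). Of 92 developmental transcription factors 43 were tested, of which 23 fell, 5 rose and 15 did not pass (23 and 6 adjusted over the list alone). Gata6 and Dlx2, an endoderm and heart factor and a forebrain factor, were at least 27.2- and 4.33-fold lower, whereas Neurod1 and the heart factor Tbx20 (0.90 ± 0.13 SE) rose. The median of these factors was -0.74 (-0.68 with bounds), -0.83, -0.80 and -0.72 in the slide-blocked and within-slide fits (camera adjusted p = 1.0e-05, and adjusted p = 0.187 with an estimated correlation). Of 47 signalling genes and cell cycle inhibitors 37 were tested, of which 18 fell, 3 rose and 16 did not pass (18 and 4 adjusted over the list alone). The growth factors Igf2 and Inhbb were at least 43.4- and 5.33-fold lower, while Bmp7 and Fgf5, also secreted factors, rose by 1.99 ± 0.20 (SE) and 1.24 ± 0.22 (SE). Their median was -1.23 (-0.83 with bounds), -1.24, -0.45 and -1.30 in the slide-blocked and within-slide fits (camera adjusted p = 6.4e-05, and adjusted p = 0.187 with an estimated correlation). Slide 1 lacks WT replicate 3, without which the median over both slides was -0.61.

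The means of the PRC2 target lists also varied with the fibroblast markers within the WT group. WT replicates 1 and 2, with fibroblast means of 0.52 and 1.45, had Hox means of -1.43 and -1.42, and WT replicates 3 and 4, with 2.57 and 3.05, had -0.61 and -0.74. In TH-MYCN spheres the Hox means lay between -5.39 and -4.33. Without WT replicates 3 and 4 the medians were -2.85 for Hox genes, -0.58 for transcription factors and -0.29 for signalling genes, and without WT replicate 3 alone -0.61 for signalling genes. Normexp with quantile normalization gave -1.20, -0.23 and -0.44 and kept all 3 lists past the test. Where only genes well above background on every array of both groups were tested, which removes members that fell below background, the medians were -0.31, 0.10 and 0.06 and none of the 3 lists passed. With every member that has a probe they were -1.97, -0.03 and -0.26.

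Of 24 tested members of the list of PRC2 and PRC1 components, the complexes that write and read the silencing mark, 8 rose, 2 fell and 14 did not pass (10 and 2 adjusted over the list alone). The list was compiled with Kdm6a and Kdm6b too, demethylases that remove the mark and are part of neither complex. Bmi1, a core subunit of PRC1, rose by 0.84 ± 0.17 (SE, n = 4 and 4) log2 and Pcgf6, another PRC1 subunit, by 0.54 ± 0.10 (SE). Ezh2, the main methyltransferase of PRC2, rose by 0.64 ± 0.17 (SE, adjusted p = 0.0193) and Suz12, a core subunit, by 0.42 ± 0.11 (SE, adjusted p = 0.0204). Ezh1, the alternative methyltransferase, fell by 0.84 ± 0.13 (SE) and Phf1, an accessory subunit, by 0.61 ± 0.12 (SE). Eed, the third core subunit of PRC2, differed by 0.36 ± 0.13 (SE, adjusted p = 0.0572). As a list the components did not pass (median 0.29, 0.16 above all genes, camera adjusted p = 0.0509, and adjusted p = 0.614 with an estimated correlation), with medians of 0.29, 0.29 and 0.27 in the slide-blocked and within-slide fits. The call for Ezh2 was lost without WT replicate 3 (adjusted p = 0.0582) and without WT replicate 4 (0.0510), and that for Suz12 without the same replicates (0.0624 and 0.0581), in ranges of 0.0022 to 0.161 and 0.0022 to 0.310 over all alternatives. The list passed without WT replicate 1 (0.0483), WT replicate 2 (0.0424), TH-MYCN replicate 2 (0.0298) or TH-MYCN replicate 3 (0.0469), in a range of 0.0278 to 0.351. In WT replicates 1 to 4 the list's mean was 2.14, 2.10, 1.99 and 1.95, and Ezh2 lay at 3.46, 3.32, 2.98 and 2.86. Both fell as the fibroblast means rose (0.52, 1.45, 2.57 and 3.05), and Suz12 lay at 2.66, 2.56, 2.31 and 2.33. Whether fewer mesenchymal cells account for these rises was not tested.

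**Figure D2:**
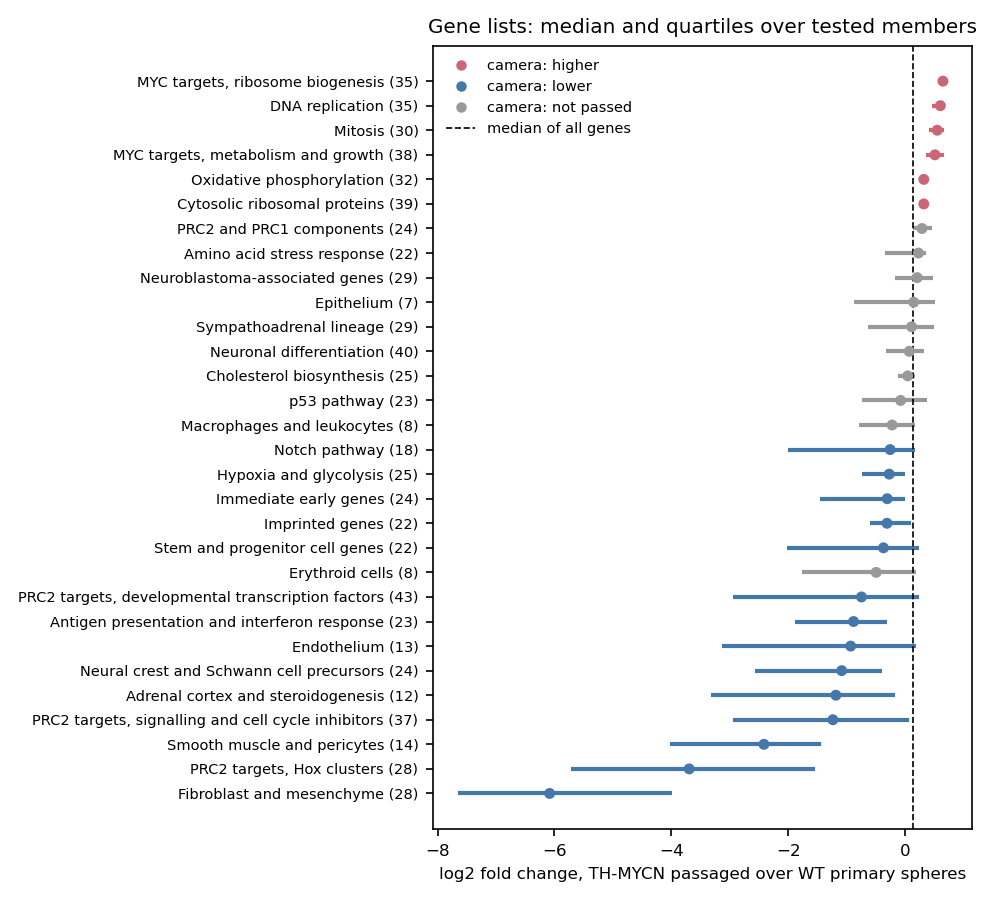
Log2 differences (TH-MYCN passaged minus WT primary, horizontal axis) of each gene list, as median (point) and quartiles (line) over its tested members. The dashed line marks the median of all genes, and colours part lists that camera passed as higher, passed as lower or did not pass. Medians run from -6.08 for fibroblast and mesenchyme markers to 0.65 for MYC targets of ribosome biogenesis, which was 0.43 under cyclic loess.

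Genes of the sympathoadrenal lineage moved in both directions. Th, tyrosine hydroxylase, whose promoter drives the transgene, rose by 1.59 ± 0.35 (SE, n = 4 and 4) log2 and the sympathetic factor Gata3 by 0.74 ± 0.17 (SE). Chgb, chromogranin B of secretory granules, fell by 2.97 ± 0.40 (SE). Of 29 tested members 7 rose, 10 fell and 12 did not pass (7 and 11 adjusted over the list alone). The median was 0.11, but the mean was -0.10 and camera's direction was lower (adjusted p = 0.155, and adjusted p = 0.646 with an estimated correlation). The median was negative under quantile normalization, cyclic loess and normexp (-0.10, -0.13 and -0.11), and also -0.19 without TH-MYCN replicate 1, -0.11 with the median of a gene's probes, -0.04 over probes in place of genes and -0.04 without both WT replicates 3 and 4. It was 0.01 without TH-MYCN replicate 3, 0.06 without WT replicate 4, 0.07 without WT replicate 3, and 0.20 and 0.19 without WT replicate 1 and TH-MYCN replicate 4. Of 40 genes of neuronal differentiation 7 rose, 9 fell and 24 did not pass (the same numbers adjusted over the list alone). Nefh, a neurofilament, and Cplx1, a synaptic protein, rose by 1.18 ± 0.12 (SE) and 1.18 ± 0.23 (SE), whereas Scg2, a granin, and Prph, the intermediate filament peripherin, fell by 2.89 ± 0.23 (SE) and 1.75 ± 0.15 (SE). This median was 0.07 with a mean of -0.10 and a lower direction in camera (adjusted p = 0.484, and adjusted p = 0.894 with an estimated correlation), and it was -0.15, -0.20 and -0.13 under the same 3 scalings. The neuronal median was -0.02 without TH-MYCN replicate 1, 0.02 without WT replicate 4, 0.13 without WT replicate 1 and 0.11 without TH-MYCN replicate 3, and it ranged from -0.20 to 0.13 over all alternatives. The sympathoadrenal and neuronal lists passed as lower under quantile normalization and normexp. Slide-blocked and within-slide medians were 0.11, 0.03 and 0.14 for the first list and 0.07, 0.07 and 0.07 for the second.

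Genes associated with neuroblastoma, of which 29 were tested and 11 stand on other lists too, gave 8 rises, 4 falls and 17 members that did not pass (the same numbers adjusted over the list alone). Lmo3, a LIM-only cofactor, rose by 1.62 ± 0.19 (SE, n = 4 and 4) log2 and the proteoglycan Ncan by 0.92 ± 0.10 (SE). In contrast, Hmga2, a chromatin protein of embryonic cells, fell by 4.28 ± 0.44 (SE; well above background on 4 of 8 TH-MYCN arrays, so in part against background) and Myc as given above. The median was 0.21, the mean -0.22 and camera's direction higher (adjusted p = 0.806, and adjusted p = 0.912 with an estimated correlation), and relative to all genes the median was 0.08, but -0.08 under quantile normalization. The median itself was -0.03 under quantile normalization and -0.02 under cyclic loess. It was 0.21, 0.18 and 0.22 in the slide-blocked and within-slide fits.

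Markers of mesenchymal cells fell most of all lists. Of 28 fibroblast and mesenchyme genes 26 fell and 2 did not pass (26 adjusted over the list alone), with a median of -6.08 (-5.14 with bounds), and -6.07, -5.71 and -6.07 with the slide as a block and on slides 1 and 2 (camera adjusted p = 2.2e-22, and adjusted p = 0.187 with an estimated correlation). In WT replicates 1 to 4 the mean over this list was 0.52, 1.45, 2.57 and 3.05, and in TH-MYCN replicates it lay between -4.51 and -4.26. Of 14 genes of smooth muscle and pericytes 12 fell and 2 did not pass (13 fell adjusted over the list alone). Acta2, smooth muscle actin, fell by 6.40 ± 0.51 (SE, n = 4 and 4) log2, mostly against background, since it was well above background on 2 of 8 TH-MYCN arrays. Anpep, a surface peptidase of pericytes, was at least 84.5-fold lower. This list's median was -2.41 (-1.88 with bounds), and -2.42, -2.39 and -2.60 in the slide-blocked and within-slide fits (camera adjusted p = 1.3e-09, and adjusted p = 0.187 with an estimated correlation). Under normexp with quantile normalization the medians of these lists were -3.76 and -1.24, and that of smooth muscle was -1.36 over genes well above background on every array of both groups.

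Markers of neural crest and Schwann cell precursors fell too. Of 24 tested members 15 fell, 3 rose and 6 did not pass (16 and 4 adjusted over the list alone). The myelin genes Pmp22 and Cnp fell by 2.27 ± 0.13 (SE, n = 4 and 4) and 0.94 ± 0.08 (SE) log2. Pou3f1, a POU factor of Schwann cells, and Nrcam, an adhesion molecule, rose by 1.48 ± 0.29 (SE) and 0.87 ± 0.14 (SE). The median was -1.08 (-0.91 with bounds), and -1.09, -1.11 and -1.41 in the slide-blocked and within-slide fits (camera adjusted p = 5.5e-06, and adjusted p = 0.187 with an estimated correlation). The list's mean in the WT replicates was -0.75, -0.64, -0.08 and -0.05, in the same order as their fibroblast means given above, and its median was -0.71 under normexp with quantile normalization and -1.69 over probes in place of genes.

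Endothelial markers gave 7 falls among 13 tested members and 6 that did not pass (7 falls adjusted over the list alone). Emcn, endomucin, and Flt1, a VEGF receptor, were at least 16.5- and 5.94-fold lower, and the list's median was -0.93 (-0.30 with bounds; camera adjusted p = 0.0085, and adjusted p = 0.265 with an estimated correlation). Genes of the adrenal cortex and steroidogenesis gave 4 falls and 2 rises among 12 (5 and 2 adjusted over the list alone), with Hsd3b1, a steroid dehydrogenase, and Mc2r, the corticotropin receptor, at least 22.6- and 17.2-fold lower and Scarb1, a lipoprotein receptor, up by 0.45 ± 0.10 (SE, n = 4 and 4) log2. This list's median was -1.18 (-0.97 with bounds; camera adjusted p = 0.0205, and adjusted p = 0.593 with an estimated correlation). In WT replicates 1 to 4 the means were -2.05, -1.72, -1.42 and -1.12 for the endothelial list and -1.69, -1.47, -1.04 and -0.77 for the macrophage list, in the same order as the fibroblast means given above. The adrenal means, -1.08, -2.98, -1.50 and -0.13, and the erythroid means, -4.08, -2.63, -2.90 and -2.72, were not in that order, and the erythroid mean of WT replicate 1 lay within the range of the TH-MYCN replicates (-4.33 to -3.92). Hsd3b1 lay at 0.96, -4.73, -1.21 and 2.06 in WT replicates 1 to 4. Its bound given above is one on the WT mean and does not hold for each WT replicate. Slide-blocked and within-slide medians were -0.91, -0.83 and -0.87 for endothelium and -1.19, -1.18 and -1.22 for the adrenal list. Of 8 erythroid genes 3 fell and 5 did not pass (4 fell adjusted over the list alone), with the embryonic globin Hbb-y at least 6.84-fold lower and a median of -0.49, and -0.45, -0.73 and -0.21 in the slide fits (camera adjusted p = 0.116, and adjusted p = 0.494 with an estimated correlation). Of 8 macrophage and leukocyte genes 1 fell (0 adjusted over the list alone in limma, 1 at an unadjusted p under 0.05), with a median of -0.22, and -0.16, -0.17 and -0.16 in the slide fits (camera adjusted p = 0.502, and adjusted p = 0.646 with an estimated correlation). The macrophage median was -0.01 without WT replicate 4, -0.14 without WT replicate 3, -0.14 without TH-MYCN replicate 2, -0.40 without WT replicate 1 and 0.12 without both WT replicates 3 and 4. Without the filter on dim probes it was -1.15 and the list passed (adjusted p = 0.0207, range 0.0207 to 0.79 over all alternatives). Of 7 epithelial genes 2 fell, the keratins Krt8 (at least 1.91-fold) and Krt18 (-1.80 ± 0.45 SE), and 1 rose, Krt14 (0.73 ± 0.16 SE), with the same numbers adjusted over the list alone, a median of 0.15, a mean of -0.30 and a lower direction in camera (adjusted p = 0.806, and adjusted p = 0.894 with an estimated correlation). The epithelial median was 0.16, 0.24 and 0.16 in the slide fits, 0.08 without WT replicate 2, and 0.03 to 0.25 over all alternatives. The erythroid median ranged from -0.78 to 0.04 over all alternatives. The endothelial call was lost under cyclic loess and normexp, the adrenal call under quantile normalization, cyclic loess, normexp, array weights and a trended robust variance, and both where genes had to be well above background on every array of both groups (endothelial median 0.19). The adrenal median was -0.76 without WT replicate 4 and -0.59 without WT replicates 3 and 4, its adjusted p was 0.0512 without TH-MYCN replicate 1 (range 5.4e-04 to 0.726), and the erythroid list passed without WT replicate 1 (adjusted p = 0.00995, range 0.0098 to 0.381).

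**Figure D3:**
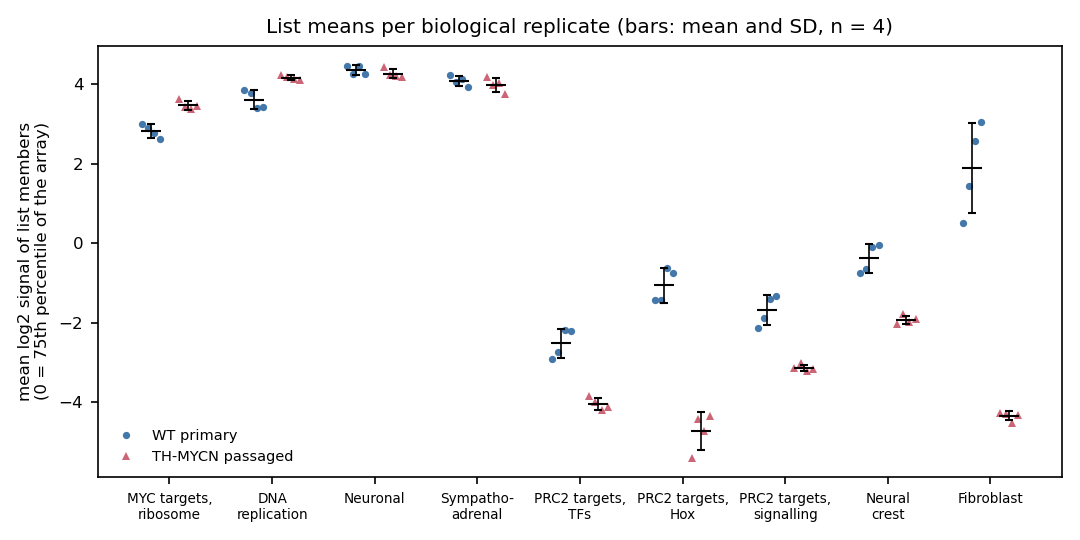
Mean log2 signal relative to each array's 75th percentile over the members of gene lists (vertical axes) in the 4 WT primary and 4 TH-MYCN passaged replicates (points), with the mean and SD of each group. The fibroblast and mesenchyme mean lies between 0.52 and 3.05 in WT and between -4.51 and -4.26 in TH-MYCN spheres, and the ribosome biogenesis mean between 2.62 and 3.01 in WT and between 3.38 and 3.64 in TH-MYCN spheres.

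Among 23 genes of antigen presentation and the interferon response 13 fell and 10 did not pass (16 fell and 1 rose adjusted over the list alone). Tap2, a peptide transporter, was at least 8.14-fold lower and the interferon-induced Ifi35 fell by 1.60 ± 0.18 (SE, n = 4 and 4) log2. The median was -0.88 (-0.69 with bounds), and -0.89, -0.68 and -0.91 in the slide-blocked and within-slide fits (camera adjusted p = 1.9e-06, and adjusted p = 0.213 with an estimated correlation). Of 24 immediate early genes 9 fell, 1 rose and 14 did not pass (the same numbers adjusted over the list alone), with Ccn2 and Klf2, targets of mechanical and serum signals, at least 27.2- and 19.4-fold lower and a median of -0.30, and -0.33, -0.34 and -0.35 in the slide fits (camera adjusted p = 9.6e-05, and adjusted p = 0.142 with an estimated correlation). The fibroblast means given above moved with both lists. The antigen presentation median was -0.49 under normexp with quantile normalization and -0.57 over genes well above background on every array of both groups.

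Of 18 genes of the Notch pathway 7 fell, 2 rose and 9 did not pass (7 and 4 adjusted over the list alone). The ligand gene Dll3 fell by 3.51 ± 0.26 (SE, n = 4 and 4) log2 and the target Heyl was at least 6.49-fold lower. The ligand Jag1 and the target Hes5 rose by 0.63 ± 0.13 (SE) and 0.54 ± 0.12 (SE). The median was -0.25, and -0.26, -0.26 and -0.30 in the slide-blocked and within-slide fits (camera adjusted p = 0.0156, and adjusted p = 0.187 with an estimated correlation). Of 22 stem and progenitor cell genes 10 fell, 4 rose and 8 did not pass (10 and 6 adjusted over the list alone). Igf2bp2, an RNA-binding protein, was at least 42.0-fold lower and the intermediate filament gene Nes fell by 2.40 ± 0.22 (SE), while Lin28b, which blocks let-7 maturation, rose by 1.14 ± 0.22 (SE). This median was -0.37, and -0.37, -0.35 and -0.40 in the slide fits (camera adjusted p = 0.0109, and adjusted p = 0.187 with an estimated correlation). Of 22 imprinted genes 6 fell, 1 rose and 15 did not pass (the same numbers adjusted over the list alone). Igf2 fell as given above, Cdkn1c, a cyclin-dependent kinase inhibitor, fell by 2.11 ± 0.21 (SE), and Slc38a4, an amino acid transporter, rose by 0.50 ± 0.11 (SE). The imprinted median was -0.31, and -0.31, -0.19 and -0.31 in the slide fits (camera adjusted p = 0.0122, and adjusted p = 0.187 with an estimated correlation). All 3 of these list calls were lost under cyclic loess, that of the stem cell list also under quantile normalization and normexp, and those of the Notch and stem cell lists over genes well above background on every array of both groups. In WT replicates 1 to 4 the means were -0.04, 0.20, 0.50 and 0.53 for the Notch list and 2.39, 2.53, 2.73 and 2.80 for the imprinted list, in the same order as the fibroblast means given above, and -0.06, 0.13, 0.04 and 0.23 for the stem cell list, which were not in that order. The Notch median was -0.40 without TH-MYCN replicate 3, and the imprinted median was -0.17 when spots that failed on 1 array were left out.

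Of 39 cytosolic ribosomal protein genes 16 rose and 23 did not pass (17 rose adjusted over the list alone), among them Rps2 at 0.49 ± 0.12 (SE, n = 4 and 4) log2. The median was 0.32, and 0.32, 0.33 and 0.32 in the slide-blocked and within-slide fits (camera adjusted p = 6.4e-05, and adjusted p = 0.614 with an estimated correlation), but relative to all genes it went from 0.19 to -0.01 under quantile normalization and normexp. Of 32 genes of oxidative phosphorylation 11 rose and 21 did not pass (0 rose adjusted over the list alone in limma, 23 at an unadjusted p under 0.05), with a median of 0.32, and 0.32, 0.30 and 0.34 in the slide fits (camera adjusted p = 5.0e-04, and adjusted p = 0.614 with an estimated correlation). In WT replicates 1 to 4, whose fibroblast means were 0.52, 1.45, 2.57 and 3.05, the means were 7.92, 7.80, 7.84 and 7.67 for ribosomal proteins and 5.98, 5.82, 5.82 and 5.67 for oxidative phosphorylation. Both list calls were lost under quantile normalization, cyclic loess and normexp, with medians of 0.04, 0.0011 and 0.02 for ribosomal proteins and 0.06, 0.05 and 0.06 for oxidative phosphorylation.

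Of 25 genes of hypoxia and glycolysis 7 fell, 2 rose and 16 did not pass (5 and 0 adjusted over the list alone in limma, 9 and 4 at an unadjusted p under 0.05). Adm, adrenomedullin, fell by 1.71 ± 0.33 (SE, n = 4 and 4) log2 and Car12, a carbonic anhydrase, by 1.68 ± 0.32 (SE). The median was -0.27, and -0.27, -0.17 and -0.26 in the slide-blocked and within-slide fits (camera adjusted p = 0.0156, and adjusted p = 0.614 with an estimated correlation), and under cyclic loess it was -0.47. It was -0.41 without WT replicate 2, -0.13 without WT replicate 3, -0.16 without TH-MYCN replicate 3 and, with no call, -0.07 without WT replicates 3 and 4, and the call was also lost with array weights and a trended robust variance. Of 23 genes of the p53 pathway 5 rose, 6 fell and 12 did not pass (6 and 6 adjusted over the list alone). Trp53, the gene of p53, and Pidd1, a death-domain protein, rose by 0.54 ± 0.10 (SE) and 0.81 ± 0.12 (SE), while Pmaip1, the apoptosis factor NOXA, was at least 3.85-fold lower and the cytokine Gdf15 fell by 1.92 ± 0.30 (SE), mostly against background (well above it on 2 of 8 TH-MYCN arrays). Its median was -0.08, and -0.08, -0.06 and -0.07 in the slide fits (camera adjusted p = 0.194, and adjusted p = 0.662 with an estimated correlation). It was 0.008 without TH-MYCN replicate 3, -0.17 without TH-MYCN replicate 4 and -0.28 under cyclic loess, the ends of its range over all alternatives being -0.28 and 0.008. Of 22 genes of the amino acid stress response 2 rose, 3 fell and 17 did not pass (the same numbers adjusted over the list alone), with Nupr1, a stress-induced nuclear protein, and Trib3, a pseudokinase, down by 4.07 ± 0.51 (SE) and 1.73 ± 0.32 (SE). This median was 0.23, the mean -0.18 and camera's direction lower (adjusted p = 0.842, and adjusted p = 0.948 with an estimated correlation), and it was 0.22, 0.21 and 0.24 in the slide fits but -0.07 under quantile normalization and cyclic loess and -0.05 under normexp. It was also 0.14 without WT replicate 4 and 0.14 without TH-MYCN replicate 1. Over WT replicates 1 to 4 Nupr1 lay at -0.61, 0.40, 0.99 and 1.28, in the order of the fibroblast means given above. Gdf15 rose in that order too, from -4.055 to -2.75. Trib3 was higher in WT replicates 3 and 4 (2.495 and 2.59) than in 1 and 2 (1.80 and 1.68). Adm, Car12, Pmaip1 and the means of the hypoxia, p53 and stress lists were not in the order of the fibroblast means. Whether fewer mesenchymal cells account for the falls of Nupr1, Gdf15 and Trib3 was not tested. Of 25 genes of cholesterol biosynthesis 1 fell, the sterol reductase gene Tm7sf2 (-0.52 ± 0.12 SE), and 24 did not pass (0 fell adjusted over the list alone in limma, 1 at an unadjusted p under 0.05), with a median of 0.05, and 0.04, 0.10 and 0.01 in the slide fits, and a lower direction in camera (adjusted p = 0.546, and adjusted p = 0.904 with an estimated correlation). The cholesterol median was -0.04 without TH-MYCN replicate 1, -0.01 without WT replicate 4, 0.01 without WT replicate 2, 0.12 without WT replicate 1 and 0.11 without TH-MYCN replicate 4, and -0.18 to 0.12 over all alternatives.

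Of the 30 lists 20 passed, 6 as higher and 14 as lower, and 0 passed with an estimated correlation (4 at an unadjusted p under 0.05), whereas fry, which tests whether a list's genes move one way on balance, passed 19. Counted over the 35 ways to split the 8 replicates into 4 and 4, 6 splits, the real one included, gave 20 or more passing lists. Of 116 named genes 15 changed their call without 1 replicate, which are Pou4f2, Ezh2 and Suz12, given above, and 12 others. Rpl5 (0.35 log2) and Sdhc (0.37), a ribosomal protein and a respiratory subunit, lost it without WT replicate 4 (adjusted p = 0.0524 and 0.0515). Psat1 (0.61), an enzyme of serine synthesis, lost it without WT replicate 3 or 4 (0.0794 for each). Ndufb5 (0.46), another respiratory subunit, lost it without WT replicate 3 or 4 or TH-MYCN replicate 2 (0.0509 to 0.0532). Adgre1 (-2.01), a macrophage receptor, lost it without WT replicate 2, 3 or 4 or TH-MYCN replicate 2 (0.0536 to 0.0666). Fdx1 (0.32), an electron carrier of steroid synthesis, lost it without these or TH-MYCN replicate 4 (0.0551 to 0.0854). Igf2bp3 (0.49), an RNA-binding protein, lost it without WT replicate 3 or 4 or TH-MYCN replicate 1, 2 or 3 (0.0568 to 0.0773). Mif (0.43), a cytokine, lost it without any replicate but WT 1 and TH-MYCN 3 (0.0524 to 0.123). Pfkfb3 (0.47), a regulator of glycolysis, lost it without any but WT 1 and TH-MYCN 4 (0.0617 to 0.116). Vldlr (0.62), a lipoprotein receptor, lost it without any but WT 3 and TH-MYCN 4 (0.0515 to 0.0821). Ccn1 (1.04), a matrix-associated signalling protein, lost it without any but TH-MYCN 3 and 4 (0.0517 to 0.0766), and Hba-x (at least 2.36-fold lower), an embryonic globin, without any but WT 1 (0.0556 to 0.0824).

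Some named genes lost their call under other settings. Th, Cplx1, Adm, Bmi1, Hbb-y, Hsd3b1, Krt18, Lin28b and Trib3 lost it without both WT replicates 3 and 4, and Gata3, Hes5, Pcgf6, Phf1, Slc38a4, Tm7sf2 and Trp53 lost it there and in a test against a change of 1.2-fold. Jag1 lost it in that test alone, Krt14 in that test and on slide 1, Rps2 in these settings and without both WT replicates, and Scarb1 in 5 of 31 settings. Eed passed in 9 of 31 settings. Among the genes given above for single replicates, Rpl5, Mif, Fdx1, Pfkfb3 and Vldlr also lost their call under quantile normalization. Their changes there were 0.11, 0.13, 0.13, 0.35 and 0.47 log2 (adjusted p = 0.20, 0.17, 0.11, 0.096 and 0.053 in limma). Over all 31 settings the call was lost in 7 for Rpl5, 17 for Mif, 13 for Fdx1, 19 for Pfkfb3 and 13 for Vldlr. For Sdhc it was lost in 4, with a lowest change of 0.13 log2.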

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

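The tests of the mesenchymal markers, of the scaling and of the streak were chosen after the results were seen, whereas the counts over other splits of the replicates were planned.

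Among 4 values of a group, a replicate stood apart in 13 of 292 sets looked at (60 of gene list means and 232 of named genes), where chance gives about 1 in 20, or 14.6 sets. TH-MYCN replicate 1, whose arrays had the lowest signal as given above, was the distant value in 5 of the 13. Its mean over the PRC2 and PRC1 components was 2.51 against 2.18 to 2.24 in the other TH-MYCN replicates, and its levels were -2.86 for Col1a2 (others -4.26 to -4.15), 5.50 for Srm (5.17 to 5.22), 1.12 for Tbx20 (0.67 to 0.73) and 1.26 for Trib3 (0.04 to 0.25). TH-MYCN replicate 4 stood apart in the stem and progenitor cell mean, at -1.22 (others -0.90), in Prph at 3.70 (4.02 to 4.07) and in Pfkfb3 at 2.19 (2.71 to 2.73). Krt14 lay at -3.64 in TH-MYCN replicate 3 (-3.85 to -3.81) and at -4.98 in WT replicate 1 (-4.40 to -4.28). WT replicate 3 stood apart in the amino acid stress mean, at 3.39 (3.27 to 3.29), and in Vldlr at 2.62 (2.27 to 2.33), and WT replicate 4 in Ppan at 4.45 (4.58 to 4.60).

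Probes without a gene name stood outside the comparison of genes and entered only the alternative with probes in place of genes. Of 12815 tested, 2059 were higher and 598 lower in TH-MYCN spheres.

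The fall of the PRC2 target lists went with a fall of mesenchymal markers (mean levels 6.35 in WT and -3.86 in TH-MYCN spheres for Col1a2, 7.03 and -0.57 for Sparc), so a loss of mesenchymal cells from the passaged spheres is a candidate explanation. A gene made by these cells alone would follow their level over the WT replicates with a slope of 1, and 27 of 27 fibroblast markers, which make up that level, and 6 of 9 fallen smooth muscle markers, above background on every WT array, had a slope of at least 0.5. Smooth muscle markers do not make up the level and followed it only in part (5 to 7 without any 1 WT replicate, lowest slope -0.38). For a single gene, a slope below 0.5 thus does not exclude a mesenchymal source. Of the Hox A and C genes that fell 1 of 12 had a slope of at least 0.5 (1 to 2 without any 1 WT replicate, median slope 0.07), which argues against mesenchymal cells as their only source. Of the Hox B genes 7 of 8 did (6 to 7, median slope 0.80), as the explanation needs, and of members outside the Hox clusters 17 of 33 (17 to 19), which leaves it open for these. Scaling is argued against by quantile normalization, cyclic loess and normexp, under which the highest median of the 3 lists was -0.27 relative to all genes. The other scalings shift each array as a whole or nearly so, which cancels in that value. Genotype and passage were not separated by the design and stay open for every list.

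The rise of the MYC target and cell cycle lists might likewise come from fewer mesenchymal cells among the rest. A line of each list mean on the linear level of mesenchymal markers over the WT replicates, read at the level of the TH-MYCN replicates, reached 0.25 of a rise of 0.65 log2 for ribosome biogenesis (0.22 to 0.27 without any 1 WT replicate), which argues against this as the whole cause there. It reached 0.13 of 0.33 for MYC targets of metabolism (0.09 to 0.18), 0.32 of 0.55 for DNA replication (0.29 to 0.41) and 0.37 of 0.53 for mitosis (0.35 to 0.41), where 4 WT replicates do not decide. The metabolism mean includes Ccnd2, which changed by -5.95 log2, and its rise lies below the list's median of 0.51. Over WT replicates 1 to 4 Ccnd2 lay at -0.30, 0.81, 1.70 and 2.08, in the order of the fibroblast means. Scaling is argued against by quantile normalization, cyclic loess and normexp, under which the lowest median of the 4 lists was 0.25 relative to all genes. The other scalings shift each array as a whole or nearly so, which cancels in that value. An effect of the transgene, of passage or of both was not tested.

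On the last array of TH-MYCN replicate 1, 91 unflagged spots that were bright on the replicate's other array lay at least 16-fold lower, against 23 at most on another array. Of these 89 lay within 5 columns of a line across the array, and at most 30 did in 1000 permutations of their columns. A streak or scratch on the array is a likely source, and it touched 74 genes with a symbol, 0 of them among the genes chosen by the rule for named genes. No biological explanation was tested, and values with such spots left out are among the alternatives.

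Over the 35 ways to split the 8 replicates into 4 and 4, the real split gave 3131 higher and 2440 lower genes, and 190 and 1537 at least 2-fold, and the highest of the other splits gave 2 in each of these counts. Only 1 split of 35, the real one, was as large for each, which is the smallest share that 35 splits can give. Chance is thus unlikely for the 4 counts if the replicates are independent, but it is not excluded. The other splits mix the 2 groups, which widens the spread within each side, so their low counts do not measure false calls. For gene lists that passed, 6 of 35 splits gave as many as the real 20, and the highest other gave 22, so chance is not excluded for the number of lists.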

How the results depend on the processing

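The fits on slide 1 alone, without WT replicates 3 and 4, and with failed spots left out were chosen after seeing the data, and the other alternatives were planned. List values below are medians of log2 changes, and a list passes at an adjusted p under 0.05 in camera. Where no reason is given, the cause was not tested.

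Over the alternatives, 0 calls reversed, where the direction of a list is that of camera and not the sign of its median. Of 128 counts 108 lay within 1.5 times the main count. Of 901 list values 854 kept their direction and their side of the threshold, 30 lost the call and 17 gained one. Of 3561 values of named genes 3377 kept both, 172 lost the call and 12 gained one. These numbers count the fit on last arrays, which is also that within slide 2, under both names.

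Among the scalings, quantile normalization ended the calls of the adrenal (-1.17), ribosomal protein (0.036), oxidative phosphorylation (0.065) and stem cell (-0.43) lists, and the sympathoadrenal (-0.10) and neuronal (-0.15) lists passed as lower. Cyclic loess gave 1564 genes higher, 125 of at least 2-fold, and ended the calls of the endothelial (-1.05), adrenal (-1.34), Notch (-0.42), ribosomal protein (0.0011), oxidative phosphorylation (0.051), stem cell (-0.56) and imprinted (-0.52) lists. Normexp with quantile normalization gave 87 genes at least 2-fold higher and 897 at least 2-fold lower. It ended the calls of the endothelial (-0.23), adrenal (-0.44), ribosomal protein (0.022), oxidative phosphorylation (0.059) and stem cell (-0.37) lists, and the sympathoadrenal (-0.11) and neuronal (-0.13) lists passed as lower. The PRC2 and PRC1 components passed when scaled to the median of probes detected on all arrays (0.25) or to spike-in controls (0.20). The median change of all genes, 0.13 in the main values, ranged from -0.06 (cyclic loess) to 0.13 (series matrix) over the other scalings.

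Asking for a signal well above background on every array of both groups removes genes that fell to background, and left 1604 genes lower, 687 of at least 2-fold. The lists of PRC2 target transcription factors (0.10), Hox clusters (-0.31), PRC2 target signalling genes (0.059), endothelium (0.19), adrenal cortex (-0.086), Notch (-0.10) and stem cells (-0.19) then did not pass, and the sympathoadrenal list (0.11) passed as lower. With every array of either group the adrenal list (-0.39) did not pass, and without a filter the macrophage list (-1.15) passed. Erythroid genes gave no value under the filters on every array, which left fewer than the 3 members a test was given. Taking probes in place of genes gave 5494 probes higher, 388 of at least 2-fold, since more features are tested, and the sympathoadrenal (-0.043) and erythroid (-0.56) lists passed as lower.

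Stricter tests lowered the counts by construction: an adjusted p under 0.01 gave 782 higher and 1451 lower, and a test against a change of 1.2-fold 473 and 1568. A trended robust variance ended the calls of the adrenal (-1.18) and hypoxia (-0.27) lists, and so did array weights (-1.04 and -0.34). With first arrays only, the PRC2 and PRC1 components passed (0.31). Slide 1 alone, which holds no array of WT replicate 3, gave 1369 genes higher. With the replicate number as a block the PRC2 and PRC1 components passed (0.29), and counts were 2987 higher and 2198 lower. The labels give no pairing by that number.

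Without 1 replicate at a time, genes higher ranged from 1491 (without WT replicate 3) to 3164 (without WT replicate 1), with 1546 without WT replicate 4 and 2012 without TH-MYCN replicate 2. The PRC2 and PRC1 components ranged from 0.24 to 0.34 and passed without WT replicate 1 or 2 or TH-MYCN replicate 2 or 3 (adjusted p = 0.0298 to 0.0483, over all alternatives 0.0278 to 0.351). The erythroid list ranged from -0.61 to -0.44 and passed without WT replicate 1 (-0.61). The adrenal list ranged from -1.69 to -0.76 and did not pass without TH-MYCN replicate 1 (-1.21). Without both WT replicates 3 and 4, which also leaves fewer samples, 439 genes were higher and 1304 lower, 122 and 1009 of at least 2-fold, and the hypoxia list (-0.071) did not pass.

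Camera with a correlation estimated from the residuals passed 0 of 30 lists, and 4 at an unadjusted p under 0.05, against 20 with the preset correlation and 19 in fry. Its adjusted p was 0.142 for Hox clusters and immediate early genes, 0.187 for PRC2 target transcription factors, PRC2 target signalling genes, neural crest, fibroblasts, smooth muscle, Notch, stem cells and imprinted genes, 0.213 for antigen presentation, 0.265 for endothelium, 0.396 for MYC targets of ribosome biogenesis, 0.506 for DNA replication, 0.507 for MYC targets of metabolism, 0.569 for mitosis, 0.593 for adrenal cortex, and 0.614 for hypoxia, ribosomal proteins and oxidative phosphorylation. Fry, which tests a list without comparing it with other genes, passed the PRC2 and PRC1 components (adjusted p = 0.0416) and ended the calls of the adrenal (0.109) and hypoxia (0.247) lists.

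Signal over background limits the falls: 50.8 to 59.7% of probes were well above background on an array, and 493 of the genes called lower were not well above background on any TH-MYCN array, so that only a bound, smaller than the fitted change, can be given for their falls.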

Other observations

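The slope limits of this part, and its genes other than those the report names, were chosen after their values were seen. Hoxa7, Hoxc9 and Ntrk3 were also members of the test against mesenchymal markers given above, and no other test of an explanation was run here.

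Some genes outside the gene lists that rose are given here as single values, and whether genes of their kinds rose as a group was not tested. Kcnk1, a potassium leak channel, rose by 2.44 ± 0.09 (SE, n = 4 and 4) log2 (adjusted p = 3.9e-06 in limma), Drd4, a dopamine receptor, by 1.83 ± 0.10 (SE) and Bdnf, a neurotrophin, by 2.07 ± 0.24 (SE). Htr4, a serotonin receptor, rose by 2.71 ± 0.63 (SE) and was well above background on 5 of 7 WT arrays and all 8 TH-MYCN arrays. The neuropeptide genes Npw and Apln rose by 1.75 ± 0.19 (SE) and 1.61 ± 0.42 (SE), and Ntsr2, a neurotensin receptor well above background on 4 of 7 WT arrays, by 1.66 ± 0.32 (SE). Gabra4 and Grin2a, receptor subunits for GABA and glutamate, were not well above background on any WT array, but on 4 and 7 of 8 TH-MYCN arrays.

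Of 210 genes that were bright in WT spheres and fell at least 4-fold, 156 had a slope of at least 0.5 on the mesenchymal markers over the WT replicates, and 26 had a slope within 0.2 of 0. These 26 include Hoxa7 and others: the Notch ligand gene Dll3 fell by 3.51 log2, the granin genes Chgb by 2.97 and Scg2 by 2.89, the intermediate filament gene Nes by 2.40, Ntrk3, the neurotrophin-3 receptor, by 2.74 and Slc18a3, the vesicular acetylcholine transporter, by 2.24. Hoxc9 fell by 5.31 ± 0.95 (SE) and the RNA-binding protein gene Igf2bp1 by 3.65 ± 0.90 (SE). Both were well above background on 6 of 8 TH-MYCN arrays, as Hoxa7 was, but they varied more among the TH-MYCN replicates. In replicates 1 to 4 Hoxc9 lay at -5.09, -1.78, -1.64 and 0.23 and Igf2bp1 at -2.49, -3.11, -1.20 and -6.17. Hoxa7 lay between -5.21 and -4.46 there.

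The TH-MYCN replicates differed among themselves at some neighbouring genes. These were picked for a wide range among the replicates and close arrays within each, so the gap between arrays shows only that the values repeat. The arrays of TH-MYCN replicate 1 had the lowest signal, as given above. Hoxd4 lay at -6.89, 1.70, -1.76 and 0.03 in TH-MYCN replicates 1 to 4, against 0.12 to 0.34 in the WT replicates, and its largest gap between arrays of a TH-MYCN replicate was 0.17. Its neighbour Hoxd3 lay at -6.58, -1.86, -4.27 and -2.39, and Hoxd9 at -7.05, -1.03, -6.05 and -1.64. Hmx2 and Hmx3, homeobox genes next to each other, were lowest in TH-MYCN replicate 1 too, at -7.18 and -6.16, against -2.62 to -0.62 and -1.09 to 0.71 in the others. The WT replicates varied as well, from -2.14 to 0.19 for Hmx2, -0.06 to 2.24 for Hmx3 and -5.34 to -2.94 for Hoxd9. They were closer together for Hoxd3 (-2.91 to -2.61) and Xlr4b (-3.52 to -3.08). Xlr4b lay at 1.58 in TH-MYCN replicate 3 and between -7.11 and -5.89 in the others, with a largest gap between arrays of 0.92. Among the 8 TH-MYCN arrays Hoxd3, Hoxd4, Hmx2 and Hmx3 were well above background on 6, Hoxd9 on 4 and Xlr4b on 2, so that their lowest levels include background. Cdkn2a, which encodes the inhibitors p16 and p19Arf, lay at 2.97, 1.91, -1.81 and 0.68, against -0.08 to 1.31 in WT. Counted over genes whose arrays lay within 1 log2 in each TH-MYCN replicate, 40 genes had a range over 4 log2 among these replicates.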
